A study of Arabidopsis lyrata with 3 samples.

How the data were processed

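SEPALLATA3 (SEP3), a MADS-domain transcription factor of floral meristems and floral organs, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in inflorescences of Arabidopsis lyrata. The antibody was raised against a peptide of the A. thaliana protein, per the series' design text. Per the labels, 2 SEP3 ChIP libraries and 1 input DNA library came from inflorescences with floral buds of stage 1 to 10 or 11. All plants were vernalised for 7 to 10 weeks and then bolted at 18 to 22 °C in long days. During the cold the plants of replicate 1 and of the input stood at 8 °C with 16 h of light and 8 h of dark. Those of replicate 2 stood at 8 °C by day and 4 °C by night, with 12 h of light and 12 h of dark. Each cold treatment has 1 ChIP library, so treatment and library cannot be told apart. A further list holds SEP3 windows of A. thaliana, re-analysed from earlier samples by the same authors.

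Each of the 3 lists gives windows with a chromosome or scaffold, a start, an end, a summit position and a score, per the file headers. The score is the authors' deposited value for a window; its formula is not given in the sources used here, and it served only to rank windows within a list and to describe them. The window length in bp is a deposited column of its own and equals end minus start plus 1 throughout. The submitters' processing notes name CASAVA, with no version. The aligner, the peak caller and their settings are not given in the sources used here. The names of the files carry the builds Araly1 for A. lyrata and TAIR10 for A. thaliana. The A. lyrata windows were called per library. How the A. thaliana samples were combined into 1 list is not given in the sources used here. The input library has no window list of its own here, and both A. lyrata lists may rest on it, so part of any overlap between them may come from a shared control. Read depth per library is unknown from these lists, so no interval that needs it was computed. Wilson intervals are given for shares of windows and cover counting error over windows only.

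No list has a false discovery rate column. The main set of each list was therefore the 2000 windows of highest score, the rule fixed for that case before the data were examined. Windows tied at the limit were taken in order of chromosome and start. The tie held 69 windows in A. lyrata replicate 1, 94 in replicate 2 and 171 in A. thaliana, of which 31, 3 and 129 fell inside the main set. A replicate 1 window was called shared if it overlapped a replicate 2 window of the main set by at least 1 bp. The overlap was compared with 1000 circular shifts of the replicate 2 windows within scaffolds, one-sided; the longest lists and the gene classes had 200 shifts. Scores of shared windows were compared by Spearman's rho and by Pearson's r of log2 scores, across windows, which are not independent replicates. The SD of rho came from 500 bootstrap draws of the windows. Where a replicate 1 window met several replicate 2 windows, the 1 of highest score was taken.

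Gene positions came from a RefSeq gene table of assembly version 1 of A. lyrata, which gives no strand and leaves the scaffold of 34221 genes unknown. The table lists genes in blocks of rising start position, and the first 9 blocks, with 33239 genes, were taken as scaffolds 1 to 9. This assignment was checked after the data were examined. The last gene of a block and the last window of its scaffold ended within 31587 bp of each other. On the 8 scaffolds tested, the shared windows, at their replicate 1 summits, were set against their own block and against the other 7. The file names and the table name the build differently, so the positions relative to genes rest on both being the same assembly, and only gene symbols and distances are printed. The planned measure, summits within 1000 bp upstream of a gene start, needs strand. It was replaced by summits outside genes within 1000 bp of either end of a gene. Summits were moved by 1000 circular shifts within scaffolds for the comparison. The share inside genes and its alternatives, the space between genes, the class of the nearest gene, the clustering of windows and the distance of the strongest windows from genes were measures chosen after the data were examined. P-values were adjusted by the Benjamini-Hochberg method within each family of measures.

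The rule for named items, also fixed before the data were examined, took at most 20 genes per species from 6 lists of 116 floral, flowering time, hormone and control genes, if they had a window. It also took the 10 shared A. lyrata windows with the smallest worse rank over both libraries and the 10 A. thaliana windows of highest score. No table used here pairs those gene names with positions in either species, so the 6 lists were not tested and no gene is named from them. The planned tests of a CArG box near the summits and of shared targets between the species were not run, since no genome sequence and no A. thaliana annotation were used here.

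Alternatives were limits of 1000, 500 and 5000 windows, all deposited windows, a reciprocal overlap of at least 50%, summits within 200 bp, each library alone, a wider distance of 3000 bp, and windows drawn at random from the replicate 2 list as the comparison. Protein-coding genes alone, draws matched for window width and all alternatives for the clustering were added after the data were examined. The overlap test and the count of summits inside genes were run on simulated data. With 2000 windows per list and 40% planted as shared, the overlap exceeded the shift mean by 39.7 percentage points. Of 40 unrelated pairs of lists with 500 windows each, 2 gave p under 0.05. The simulated windows had equal widths and were placed at random along the scaffolds, while deposited windows vary in width and lie unevenly. The overlap test was thus not tried on unrelated lists that prefer the same kind of position. A planted 20% of summits inside genes was counted as 20%. These points were placed with the same gene positions that counted them, so the result was fixed in advance. No shifts were run on them, so the position test itself was not tried on simulated data. The spacing of the scores was fitted from low to high scores with a tolerance of 0.0075. This replaced a first fit that did not follow the spacing up to the highest scores. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.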

Results

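SEP3 ChIP signal was recorded as 2 window lists from A. lyrata inflorescences, 1 per ChIP library, and 1 window list for A. thaliana. The A. lyrata replicate 1 list held 93693 windows, which covered 39.7 Mb or 20.2% of the 9 scaffolds. The replicate 2 list held 64504 windows and covered 15.2 Mb or 7.78%. The A. thaliana list held 14707 windows on 5 chromosomes and covered 3.82 Mb or 3.21%. The lists began at the same lowest score and rose to 57.62 in replicate 1, 73.31 in replicate 2 and 54.87 in A. thaliana. A score of at least 10 was reached by 238, 165 and 212 windows in that order. Most listed windows were weak, with median scores of 1.42, 1.20 and 1.42. The 2000 strongest windows, the main set of each list, started at scores of 4.36, 2.78 and 3.12 and had median widths of 1201, 618.5 and 512 bp. The scores are the authors' own and their scale is not known to be shared between lists.

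The first comparison asks which strong windows were found in both A. lyrata libraries. Of the 2000 strongest replicate 1 windows, 1188 overlapped a window among the 2000 strongest of replicate 2, a share of 59.4% (95% Wilson interval 57.2 to 61.5%). Shifted windows overlapped in 2.17% on average, 27.3-fold less, and in 3.55% at most. The strongest sites overlapped to a like extent, with 58 of the top 100 and 278 of the top 500 windows shared. The 2 summits of a shared pair lay a median of 32 bp apart, and 1136 pairs (95.6%) had summits within 200 bp of each other. With partners of any strength counted, 1998 of the 2000 replicate 1 windows (99.9%) met some replicate 2 window, against 37.2% after shifts. Likewise 1914 of the 2000 replicate 2 windows (95.7%) met some replicate 1 window, against 43.1%. Of the 796 replicate 2 windows that met no window of the replicate 1 main set, 86 met no replicate 1 window at all. The overlap of the main sets exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). The libraries may share an input control, and the test compares 2 lists, so it does not measure how much binding varies between plants.

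**Figure D1:**
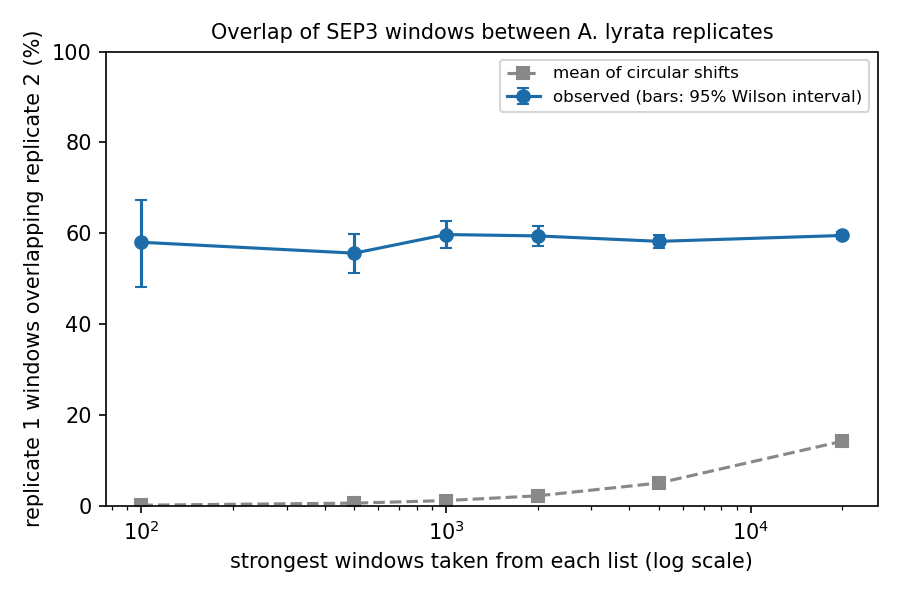
Percent of the strongest replicate 1 windows that overlap an equally long list of the strongest replicate 2 windows (vertical axis) against the number of windows taken from each list (log horizontal axis), with 95% Wilson intervals, and the mean of circular shifts in grey. The observed share lies between 55.6 and 59.7% for lists of 100 to 20000 windows, while the shift mean rises from 0.11 to 14.2%.

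The 10 shared windows with the smallest worse rank over both libraries all lay outside annotated genes. The first was on scaffold 4 from 2800561 to 2801211, with scores of 57.62 in replicate 1 and 63.67 in replicate 2. Its summit was 9174 bp from LOC9314819 on one side and 18776 bp from LOC9316647 on the other. Another window on scaffold 4, from 2833770 to 2834481, scored 39.66 and 40 and lay 1252 bp from LOC9316650 and 5079 bp from LOC9314820. The remaining scaffold 4 window, from 1506257 to 1506992, scored 52.64 and 43.05 and lay 1455 bp from LOC110229530, a long non-coding RNA gene, with LOC110228932, the next gene on the other side, 41786 bp away. The scaffold 5 window from 11300819 to 11301712 scored 47.58 and 52.75 and lay 2759 bp from LOC9313422. The scaffold 2 window from 13543858 to 13545120 scored 34.35 and 55.80 and lay 2322 bp from LOC9324761. On scaffold 6 the window from 22312509 to 22313278 scored 32.88 and 43.41 and lay 1342 bp from LOC9308753. On scaffold 3 the window from 14787817 to 14788627 scored 51.61 and 40.91 and lay 3947 bp from LOC9319809. Coordinates are those of the window in replicate 1, on the build the files call Araly1, and all named neighbours but LOC110229530 are protein-coding.

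Scaffold 7 held 3 of these 10 windows. The window from 18837935 to 18838902 scored 36.40 and 50.61 and lay 8312 bp from LOC9306524 and 10951 bp from LOC9304517. The window from 19132308 to 19133582 scored 39.85 and 58.48 and lay 3400 bp from LOC9306535. The window from 19185099 to 19186235 scored 32.30 and 58.67, and its summit was 11545 bp from LOC9304529 and 26348 bp from LOC110226155.

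**Figure D2:**
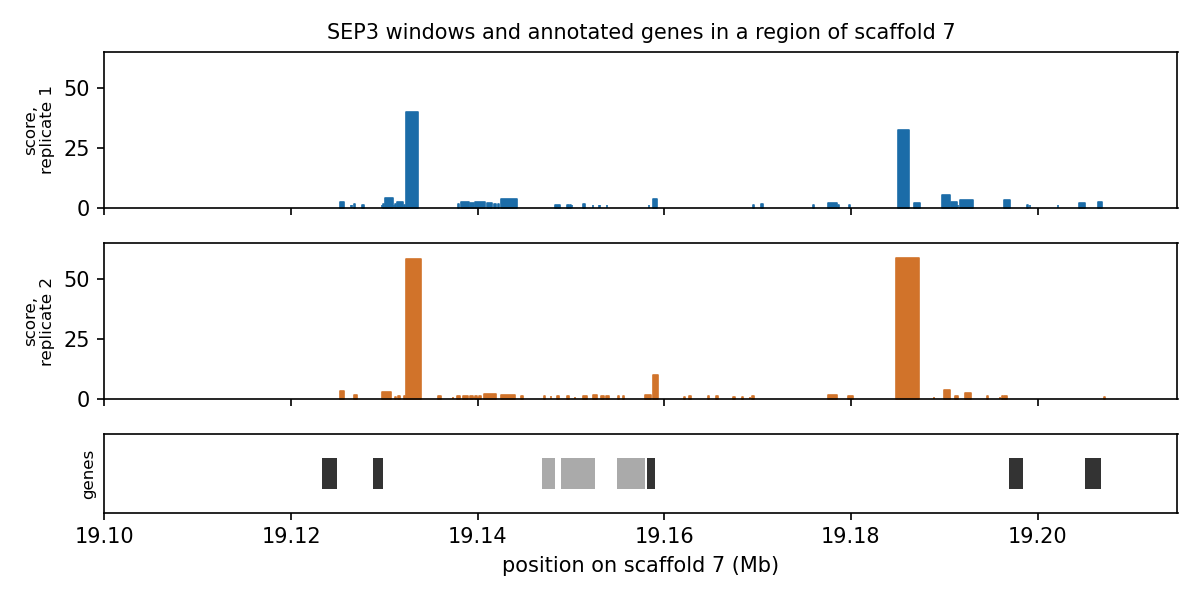
Windows of replicate 1 (blue) and replicate 2 (orange) drawn from start to end with the score as height (no unit), and annotated genes (black protein-coding, grey other classes), along scaffold 7 from 19.1 to 19.215 Mb. The windows with scores of 39.85 and 58.48, and of 32.30 and 58.67, stand in spaces between the 8 genes of the region.

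Among the sites in both main sets, those with a higher score in 1 library tended to have a higher score in the other. Across the 1188 shared windows Spearman's rho was 0.632 (bootstrap SD 0.0199) and Pearson's r of log2 scores was 0.765. The replicate 1 score was the higher in 1006 pairs and the replicate 2 score in 180, with a median log2 difference, replicate 2 minus replicate 1, of -0.61. Among the 278 pairs in the top 500 of both lists the median difference was -0.26 and replicate 2 was higher in 108. These directions are partly built in by the limits of the sets. The main sets began at scores of 4.36 in replicate 1 and 2.78 in replicate 2. A pair with a replicate 2 score under 4.36 could only come out higher in replicate 1. The median score of the replicate 2 windows that met the replicate 1 main set was 4.19. The top 500 began at 7.37 in replicate 1 and 5.04 in replicate 2. Windows were wider in replicate 1, with medians of 1096.5 against 685.5 bp. No p-value was taken across windows, and since the scale of the scores may differ between libraries, the differences do not measure occupancy.

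**Figure D3:**
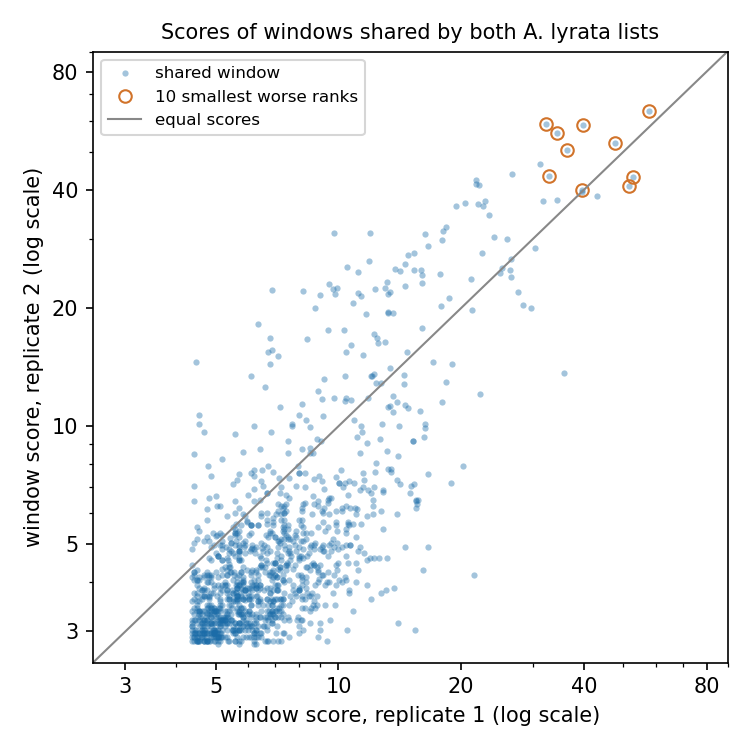
Score of each of the 1188 shared windows in replicate 1 (horizontal) and replicate 2 (vertical), both without unit and on log axes, with the line of equal scores and the 10 windows of smallest worse rank circled. Most points, 1006 of 1188, lie below the line, and the circled windows reach from 32.30 to 57.62 in replicate 1 and from 40 to 63.67 in replicate 2. The main sets start at scores of 4.36 in replicate 1 and 2.78 in replicate 2, so part of the excess below the line is built in.

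The next comparison asks where the shared sites lay relative to genes. Taken as a whole, shared summits were less frequent inside genes, and more frequent just outside them, than shifted positions. Of the 1188 summits, 241 (20.3%) lay inside an annotated gene, against 41.4% ± 2.0 (SD over shifts) after circular shifts, and genes covered 41.2% of the scaffolds. A further 472 (39.7%) lay outside genes within 1000 bp of a gene end, against 17.7% after shifts, and 754 (63.5%) within 3000 bp, against 32.3%. Only 193 (16.2%) lay more than 3000 bp from any gene, against 26.3%. The median distance of the 947 summits outside genes to the nearest gene end was 1022 bp. The spaces between genes that held them had a median length of 5760 bp, against 11209 bp after shifts. The strongest shared windows differed from the whole. Of the 50 with the smallest worse rank, 86% lay outside genes and more than 1000 bp from one, and 10% inside a gene. The excess just outside genes was thus not seen among these 50.

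The share within 1000 bp exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give), and the share inside genes lay below all of them (two-sided permutation p = 0.002, the smallest they can give; adjusted p = 0.0027 over 8 measures). Of the 947 summits outside genes, 545 (57.6%) lay in spaces longer than 5000 bp, against 72.9% after shifts (two-sided permutation p = 0.002, adjusted p = 0.0027). Taken over all 1188 summits, inside genes or not, as it was first computed, that share was 45.9% against 42.7% and did not pass (two-sided permutation p = 0.20, adjusted p = 0.20). The length of the space around summits within 1000 bp of a gene end did not pass, with 2620.5 against 3001 bp (two-sided permutation p = 0.15, adjusted p = 0.17). Without strand, the upstream and downstream sides of a gene were not separated. The scaffold of each gene was inferred from the order of the gene table.

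**Figure D4:**
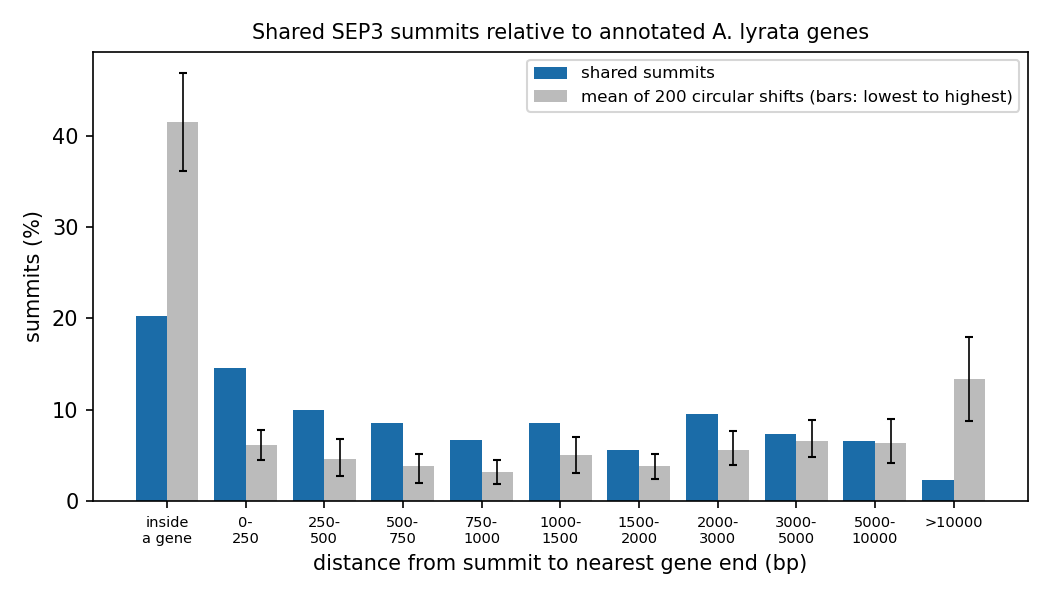
Percent of the 1188 shared summits (blue) in classes of distance from the nearest gene end in bp (horizontal axis), beside the mean of 200 circular shifts (grey, bars from the lowest to the highest shift). Summits inside genes make up 20.3%, below all shifts, and each class up to 1000 bp lies above its shifts.

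The nearest gene of a shared summit was protein-coding in 1094 of 1188 cases (92.1%), against 84.3% after shifts. Long non-coding RNA genes were nearest in 58 cases (4.88%, against 10.3%) and pseudogenes in 30 (2.53%, against 4.83%). These 3 classes differed from all 200 shifts (two-sided permutation p = 0.00995 each, the smallest they can give; adjusted p = 0.0133 over 4 classes). Transfer RNA genes, nearest in 6 cases (0.505%), did not pass the same permutation test against 0.391% after shifts (p = 0.71, adjusted p = 0.71). Shifted positions were not matched for distance to genes: 13.3% lay more than 10000 bp from one, against 2.36% of the shared summits. The difference in gene class was not separated from that in position. Of 29018 protein-coding genes, 1577 (5.43%) had a shared summit inside them or within 3000 bp, 67 of them had 2 such summits and none had 3.

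The share of summits inside genes was low for strong and intermediate windows of both libraries and higher among the weakest. Beyond rank 50000 it lay above the 41.2% of scaffold length inside genes in replicate 1, and in replicate 2 it stayed below. In replicate 1, 25.2% of the top 500 summits, 22.1% of those below rank 500 down to 2000 and 20.8% of those below rank 5000 down to 20000 lay inside genes. The share was 35.1% from there to rank 50000 and 54.3% beyond. In replicate 2 the same ranks gave 20.6, 21.9, 23.4, 34.0 and 39.4% (95% Wilson interval of the last 38.6 to 40.2%). Windows beyond rank 50000 scored at most 1.36 in replicate 1 and 1.07 in replicate 2, with median widths of 81 and 23 bp. Lists of different length were not compared rank by rank. Among the 2000 strongest replicate 1 windows, the 812 that did not overlap the replicate 2 main set lay inside genes in 26.7% (95% Wilson interval 23.8 to 29.9%), against 20.3% (18.1 to 22.7%) of the shared ones. The like shares of replicate 2 were 23.2% (20.4 to 26.3%) and 20.4% (18.3 to 22.8%), with overlapping intervals, so the difference was clear in replicate 1 only.

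**Figure D5:**
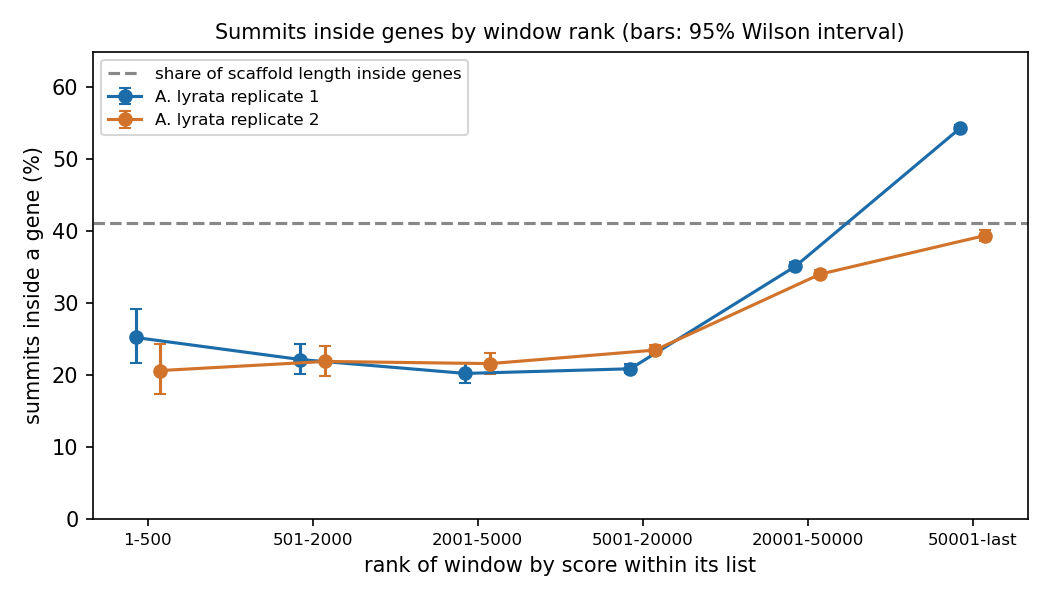
Percent of summits inside a gene (vertical axis, with 95% Wilson intervals) by rank of the window within its own list (horizontal axis), for replicate 1 (blue) and replicate 2 (orange), with the 41.2% of scaffold length inside genes as a dashed line. Shares stay between 20.2 and 25.2% up to rank 20000 and reach 54.3% in replicate 1 and 39.4% in replicate 2 beyond rank 50000.

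The A. thaliana list was included by the authors for comparison between the species. Its strongest window lay on chromosome 5 from 17549773 to 17550522 with a score of 54.87, followed by windows on chromosome 5 from 26805293 to 26805995 (39.44) and on chromosome 2 from 12940913 to 12941506 (33.23). Chromosome 1 held windows from 7930017 to 7930783 with a score of 30.22 and from 3100573 to 3101665 with a score of 28.90. Chromosome 4 held windows from 2234480 to 2235151, from 14902492 to 14903189 and from 10288342 to 10289007, with scores of 30.03, 28.15 and 27.02. The remaining windows of the top 10 lay on chromosome 5 from 669939 to 670583 and from 8920577 to 8921215, with scores of 30.22 and 26.64. Coordinates are on TAIR10, as the file names the build, and the genes beside these windows were not analysed here. The list held 123 windows per Mb, against 478 and 329 in the A. lyrata libraries. These densities follow the number of windows each list retained, and whether the same genes were bound in both species was not analysed here.

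At the main limit of 2000 windows, strong SEP3 windows had another strong window nearby more often than windows of any strength from the same list. In A. thaliana 914 of the 2000 strongest summits (45.7%) had another within 10000 bp, against 36.3% when 2000 windows were drawn at random from the same list. In A. lyrata replicate 2 the share was 30.3% of 2000, against 23.6% in random draws. In replicate 1 it was 496 of 2000 (24.8%), against 22.5%, and among the shared windows 198 of 1188 (16.7%), against 14.04%. One-sided permutation tests with 1000 draws gave p = 0.001, the smallest they can give, for A. thaliana and replicate 2 (adjusted p = 0.002 over 4 tests), p = 0.033 for replicate 1 and p = 0.036 for the shared windows (adjusted p = 0.036 for each). The replicate 1 result did not pass its permutation test with the top 1000 (13.3%, p = 0.16) or the top 500 windows (8%, p = 0.12). The replicate 2 set includes the 86 windows that met no replicate 1 window. With summits within 10000 bp joined, these 86 lay at 52 places and the other 1914 at 1607. Clustering was not computed without the 86. The shares of different lists were not compared with each other, since the genomes and list lengths differ.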

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

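The share inside genes with all its alternatives, protein-coding genes alone, the width-matched draws and the tests of clustering were chosen after the results were seen. The alternatives for the overlap, the score correlation and the share near a gene end were otherwise set before. The overlap of the A. lyrata libraries stayed above its comparison under every alternative run, from 40.2% for all deposited windows (18.5% after shifts) and 40.4% for a reciprocal overlap of at least 50% (0.366%) to 59.7% for the top 1000 windows (1.13%). The share of summits within 1000 bp of a gene end ranged from 31.7% for the top 500 windows to 40.9% for the top 5000, and it was 36.8 to 40.25% in either library alone. The share inside genes stayed between 19.02 and 22.9%, below its shifts throughout. The score correlation of the shared windows moved by more than its bootstrap SD, from 0.632 to 0.596 with the top 1000 windows, 0.672 with the top 500 and 0.660 with reciprocal overlap; the cause was not tested. Clustering of replicate 1 windows no longer passed with the top 1000 windows (13.3% against 11.9% in random draws) or the top 500 (8% against 6.12%), and passed with the top 5000 (49.6% against 46.9%); the cause was not tested. In A. thaliana and replicate 2 it passed at each limit run. For the gene lists, the CArG box and the targets shared between species, neither the results nor their 27 other settings were run. No paired analysis was possible because the input library has no window list of its own here. Read depth is unknown, so the lists cannot show which windows a deeper library would add.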

Other observations

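The tests on distance of the strongest windows, on gene position by rank, on the scaffold of the genes and on gene-poor DNA were chosen only after the results were seen. The 50 shared A. lyrata windows of smallest worse rank stood farther from genes than the other shared windows. They include the 10 named windows, all more than 1000 bp from a gene, which were seen before the test was chosen. Its p-value is therefore not that of a fresh test. Of these 50, 43 (86%) lay outside genes and more than 1000 bp from one, against 38.0% of the other 1138 shared windows (two-sided permutation p = 0.0002, the smallest that 10000 permutations can give; adjusted p = 0.0003 over 9 tests). The share was 69% for the top 100 and 56.5% for the top 200, so it declined as weaker windows were added. It was 86% with protein-coding genes alone, 72% for the top 50 of replicate 1 and 88% for the top 50 of replicate 2. The space between genes that held these summits had a median length of 18513 bp for the top 50, against 5496 bp for the others. The share inside genes, 10% of the top 50 against 20.7% of the others, did not pass (two-sided permutation p = 0.083, adjusted p = 0.11). The replicate 2 top 50 behind the 88% includes its windows of rank 1 and 42, which met no replicate 1 window. No cause of the distance, technical or biological, was tested, and stacking of reads on gene-poor DNA was not measured.

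The scores of each list mostly fell on regular steps. The step was 0.0639 in A. lyrata replicate 1, 0.0610 in replicate 2 and 0.188 in A. thaliana, with 88.2, 96.9 and 99.5% of scores within 0.0075 of a step, against 23.5, 24.6 and 7.97% by chance. From the lowest score to the lower limit of the main set there were 52.4, 29.0 and 11.2 steps.

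The overlap of the strongest windows may reflect regions that both whole lists share at any score, since windows cover a large part of the scaffolds. Replicate 2 windows below its strongest 2000, drawn with matched widths, met the strongest replicate 1 windows in 10.1% on average and in 11.9% at most of 1000 draws, against the observed 59.4%. Windows of a list lay at least 100 bp apart, so the drawn windows could not lie where the strongest replicate 2 windows did. Part of the lower share was therefore built in. Weaker windows of replicate 1 were not drawn. A shared input control stays open, as does SEP3 binding as the biological explanation; neither was tested, because the input has no list of its own here.

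The low share of shared summits inside genes might come from genes placed on the wrong scaffold. This is not what the check of the gene blocks showed: on 8 of 8 scaffolds the own block gave the lowest share of summits inside genes, 13.9 to 25.2%, against 27.9 to 55.4% for the 56 pairings with another block. A preference for gene ends could instead belong to listed windows of any strength. In replicate 1, 20.8% of summits below rank 5000 down to 20000 lay inside genes, close to the 20.3% of the shared summits, but 35.1% did from there to rank 50000 and 54.3% beyond, and in replicate 2 the last classes gave 34.0 and 39.4%. The low share inside genes was thus not found at every strength. The share within 1000 bp of a gene end was 44% in replicate 1 below rank 5000 down to 20000, then 36.3 and 23.7%. The last classes of replicate 2 gave 32.75 and 28.7%, against 17.7% after shifts of the shared summits. Shifts of either main set alone also gave 17.7%. In every rank class of both lists the share near a gene end, from 23.7 to 44%, lay above that value. The excess near gene ends was therefore not particular to the shared windows, though no rank class was shifted on its own. Whether accessible chromatin without SEP3 would give the same position stays open, and no biological explanation was tested.

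In replicate 2, 86 of the 2000 strongest windows met no replicate 1 window at all, among them the window of highest score, 73.31, on scaffold 6 from 17177792 to 17178185, whose nearest gene, LOC9310542, lay 29947 bp away. Of the top 200 windows, 13 of replicate 2 and 0 of replicate 1 were absent from the other list. The 86 windows were narrow, with a median of 175.5 bp against 631.5 bp for the other 1914, and 58 (67.4%) lay more than 3000 bp from any gene, against 313 (16.4%) of the others. With summits within 10000 bp joined, this held for 29 of 52 places (55.8%) against 232 of 1607 (14.4%). Reads stacked on gene-poor DNA stay open as a technical explanation, since stacking was not measured and the distance had been seen before it was tested. Control signal above a background floor was tested as scores off the regular steps, on the assumption, which no source used here states, that steps mark windows with the control at a fixed floor. Scores off the steps were found in 5 of the 86 (5.81%) and 3.45% of the others (two-sided Fisher's exact p = 0.229), so that explanation was not decided. The upper limit of the exact two-sided 95% interval for the 86 was 13.0%. The different cold treatment of the plants, the biological explanation, cannot be told apart from the library, with 1 library per treatment.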
